A study of Saccharomyces cerevisiae with 103 samples.

How the data were processed

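The samples were cultures of SK1, a strain of the budding yeast Saccharomyces cerevisiae that sporulates rapidly, per the labels. In sporulation medium (SPO), which holds acetate and little nitrogen, diploid SK1 cells enter meiosis and form spores. The series holds 103 libraries, of which 50 are RNA-seq libraries, 50 are libraries of poly(A) tags that measure the length of the poly(A) tail of each mRNA, and 3 are RNA-seq libraries made by another order of steps. Groups and replicate numbers were taken from the sample titles, and no sample was left without a group.

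The RNA-seq count tables were deposited as raw counts per gene, 1 column per library. Per the labels' protocols, an adapter was ligated to the 3' end of the RNA, ribosomal RNA was removed, and the RNA was then fragmented. The 3 other RNA-seq libraries were fragmented before ligation, per the labels' protocols, and were also deposited as raw counts. The poly(A) tag counts per gene were deposited by the authors as whole numbers, and per the labels' protocols these libraries were made by poly(A) selection, fragmentation and ligation of a 3' adapter. The authors also deposited the mean poly(A) tail length of each gene in each library, in nucleotides (nt), not scaled between libraries. From the values themselves, each such mean is taken over whole tail lengths of at least 4 nt, 1 for each tag of the gene. A deposited table of 3' bias gives a ratio per gene for the 3 libraries fragmented before ligation, over 100 nt or over 10% of the gene per the file headers. Its formula is not given in the sources used here and its gene labels could not be joined to the other tables, so only the distribution per library was used.

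Alignment with STAR 2.5.3a, bedtools (2.26.0 for the poly(A) tags), edgeR and the genome build sacCer3 are named per the submitters' processing notes. How a tail end was called, whether tags were deduplicated and whether reads were counted by strand are not given in the sources used here. Overlapping genes and near-identical copies, such as most ribosomal protein gene pairs, histone gene pairs and CUP1-1 and CUP1-2, can share or lose reads, and values of such genes are uncertain. Neither assay is stated to use molecular identifiers, so intervals and floors cover counting error only. An empty cell in the tag and tail tables was read as 0 tags, since the smallest count listed is 1. The tables hold 6692 genes, of which 6008 matched the reference table of gene names by systematic name. Coordinates come from the R64 reference annotation, the assembly that sacCer3 stands for. Untranslated regions were not used.

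RNA-seq counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization and the filterByExpr filter, in 1 model of group means per experiment. Mean tail lengths were tested with limma 3.58.1 on the linear scale. A tail value that rested on under 20 tags was set to missing, and a gene was tested where every library of the compared groups had a value. The variance prior followed the mean log2 tag count and was robust. Benjamini-Hochberg adjusted p under 0.05 counted as changed in both tests. CPM is the read count divided by the TMM-adjusted total of its library, on the usual scale, and the mean ± SD given with it is over n = 2 libraries. Log2 fold changes and SE come from the fit. Groups had 2 libraries in the first 2 experiments and 1 library elsewhere. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The replicate numbers were not treated as pairs.

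For pairs of single libraries no test was made and differences are given as higher or lower. They had no replicate check. A yardstick came from the replicate libraries of the sporulation time course. The 95th percentile of their per-gene difference had a median over times of 8.33 nt in tail length and 0.65 in log2 CPM. Across times it ran from 5.33 to 12.6 nt and from 0.57 to 1.23. In the return to growth, which had more tags, it ran from 8.69 to 12.45 nt and from 0.59 to 2.075. Shares beyond the yardstick therefore depend on the replicates it is taken from. Those yardsticks describe libraries of other depth. Log2 differences of single libraries used a prior count of 2 and genes with a mean of at least 10 counts. A gene list's median was placed as a percentile among 10000 random lists of the same size matched on mean expression, as a description of these libraries. These random lists could draw members of the list itself. The medians of matched random lists given in the text come from a second draw that left the list's own members out, added after the data were seen.

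Gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. The 14 lists were early meiotic genes, middle meiotic genes, late sporulation genes, cytosolic ribosomal protein genes, ribosome biogenesis genes, glycolysis and fermentation genes, genes of gluconeogenesis, the glyoxylate cycle and acetate use, respiration genes, stress response genes, mRNA decay machinery genes, histone genes, copper response genes, mitotic G1 cyclin genes, and haploid-specific genes as markers of another cell type. The lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and with fry. For tails these list tests used only genes with a value in every library of the experiment. Those were 244 genes in the time course and 1229 in the return to growth. The member counts given beside a tail list can therefore be larger than the number that camera used. Adjusted p-values of lists below are from camera at the preset correlation unless the estimated correlation is named. Calls of lists that were lost with the estimated correlation have that p beside them.

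For each tested main comparison the text names from the 5 largest increases and 5 largest decreases past the threshold with a mean log2 CPM of at least 5 or a mean of at least 100 tags and the same direction in every pairing of libraries, then 2 members of each list, and always CCR4, POP2 and XRN1. The same rule was applied 5 min after transfer. For pairs of single libraries it names from the 3 largest differences each way among genes with at least 100 tags or 50 CPM in both libraries, and 2 members of each list outside the percentiles 2.5 to 97.5. CUP1-2 was named after its values were seen, because CUP1-1 had 0 RNA-seq counts in every library. A fold against libraries at 0 counts is a bound from a floor of 3 counts over the group. Against 1 to 3 counts the ratio of counts over TMM-adjusted totals is given with its 95% counting interval.

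Alternatives included DESeq2 1.42.0, RLE factors, no filter, the replicate number as a block, a 2-fold threshold, tag minimums of 10 and 50, log2 tail lengths, centring each library on its median, weights by tag count and leaving out each library. After the data were seen, 6 were added, namely a correlation over genes with shorter tails, random lists without the list's own members, library sizes alone, centring together with the block, each replicate number alone and a robust edgeR prior. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 served for the remaining steps.

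The tests were first run on simulated data. For 5 h against 0 h over 6269 genes, the RNA test recovered 23.9% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 93.9% of those changed 4-fold, with 1.46% false calls. For 20 min in rich medium after 1 h over 6109 genes these shares were 29.9%, 86.6% and 100%, and after 7 h they were 16.4%, 46.3% and 87.9%. The tail test at 5 h over 559 genes recovered 5.97% of changes of 3 nt, 34.3% of 6 nt and 77.3% of 12 nt. At 20 min the recovery of 3, 6 and 12 nt was 1.49%, 7.46% and 65.2% over 1411 genes after 1 h, and 0%, 4.48% and 45.5% over 2559 genes after 7 h. A simulated list shifted by 1 log2 unit reached percentile 100, and 5% of 200 unshifted lists lay outside the percentiles 2.5 to 97.5. Genes were simulated independently and lists drawn at random there. That share therefore does not show how often a list whose genes vary together lies outside.

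Depth limits what the tail tests can show. Totals of poly(A) tags per library ran from 71930 to 314734 in the time course and from 452277 to 1357096 in the return to growth, against 1715150 to 8926553 in the decay mutants. No pair of libraries held identical values.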

Results

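Poly(A) tail lengths and RNA levels were measured in SK1 yeast in 5 experiments. The first followed sporulation hour by hour from 0 to 9 h in SPO, with 2 RNA-seq and 2 poly(A) tag libraries per hour. In the second, cells were returned from SPO to rich medium (YPD) after 1 h or 7 h and sampled before transfer and after 5 and 20 min, again with 2 libraries of each kind per group. The third set wild type beside strains lacking CCR4, POP2 or XRN1 in vegetative growth, after premeiotic growth and at 5 h in SPO, with 1 library of each kind per strain and stage. The fourth used an Xrn1 degron strain, in which auxin triggers degradation of the protein, and the fifth a strain with CCR4 under a copper-inducible promoter, each with a wild-type control and 1 library of each kind per time. Total RNA-seq counts per library ran from 364038 to 3821895 in the time course, from 132594 to 4689131 in the return to growth, from 178152 to 1596718 in the mutants, from 1299404 to 4583279 in the degron experiment and from 1426300 to 2011448 in the Ccr4 experiment. Tag totals were 71930 to 314734, 452277 to 1357096 and 1715150 to 8926553 in the first 3 experiments, 3056546 to 5051943 in the degron experiment and 791068 to 1494132 in the Ccr4 experiment. The shallowest RNA-seq library, with 132594 counts, was replicate 2 before transfer at 7 h.

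Ccr4 and Pop2 are the deadenylases of the Ccr4-Not complex, which shorten poly(A) tails, and Xrn1 is the cytoplasmic 5' to 3' exonuclease that degrades decapped mRNA. CCR4 (YAL021C) lies on chromosome I from 110846 to 113359, POP2 (YNR052C) on chromosome XIV from 719346 to 720647 and XRN1 (YGL173C) on chromosome VII from 175527 to 180113. Each lies on the minus strand with 1 coding exon, in R64 coordinates. The near-identical metallothionein genes CUP1-1 (YHR053C) and CUP1-2 (YHR055C) lie on chromosome VIII from 212535 to 212720 and from 214533 to 214718.

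The time course asks which mRNAs and tails change as cells pass from premeiotic growth through meiosis. At 5 h in SPO, genes of the meiotic lists rose while genes of ribosomes and glycolysis fell. All 30 early meiotic genes rose, with a median log2 change of 5.10, and all 33 middle genes rose with a median of 5.17. SPO11, which makes the double-strand breaks of recombination, rose by 6.32 log2 units to a mean of 222 CPM from 2.75. PES4, a middle gene, went from 24.0 ± 23.0 to 1961 ± 479 CPM (n = 2, log2 6.34). Among 137 cytosolic ribosomal protein genes 135 fell and 1 rose, with a median of -2.39, and all 16 genes of glycolysis and fermentation fell, with a median of -4.61. TDH1, which encodes glyceraldehyde-3-phosphate dehydrogenase, fell by 7.07 log2 units (SE 0.41, adjusted p = 3.48e-11, edgeR), from 4162 ± 128 to 30.8 ± 0.563 CPM.

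Other large increases at 5 h were YGL138C (log2 7.23, SE 0.56, adjusted p = 1.58e-09), SRL4 (6.77), LDS1 (6.79) and LDS2 (6.73), the last 2 being spore lipid droplet proteins of the late list. YCL021W-A had 3 counts at 0 h and a ratio of 139 (95% interval 47.5 to 673). YDR015C rose by 6.85 log2 units beside its overlapping neighbour HED1 (6.27), an early gene, and the pair could not be told apart. The hexose transporter gene HXT6 fell by 5.95, the glycolytic genes GPM1 and ENO2 by 5.72 and 5.45, and YKL153W, which overlaps GPM1, by 5.77. All 29 ribosome biogenesis genes fell (median -2.13), including NSR1 (-4.76) and NOP58 (-3.36). Of the ribosomal protein genes, RPS22A (-3.95) and RPS3 (-3.90) fell most among those past the threshold.

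In the late list 16 genes rose and 1 fell (median 4.72). Of 11 haploid-specific genes, markers of a cell type these diploids should not be, 6 rose and 1 fell, with MFA1 at 21.1 ± 1.19 CPM against 1.46 ± 2.06. Adjusted over the list alone, these counts were 7 and 1 for haploid-specific genes, 136 lower and 1 higher for ribosomal protein genes, and the same as over all genes for the other lists named so far. The camera test passed for early (adjusted p = 1.86e-23), middle (4.08e-15) and late genes (9.59e-07), ribosomal protein genes (6.16e-26), ribosome biogenesis (1.04e-08), glycolysis (6.72e-11) and haploid-specific genes (0.0324). All but early genes (0.00885) were lost with the estimate, at adjusted p = 0.163 with an estimated correlation for middle and late genes, 0.0556 for ribosomal protein genes, ribosome biogenesis and glycolysis, and 0.0913 for haploid-specific genes.

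The remaining lists at 5 h did not pass camera. Of 16 gluconeogenesis, glyoxylate and acetate genes 6 rose and 7 fell, and here the median was 0.18, the mean -0.42 and the camera direction down (adjusted p = 0.762). FBP1, the gluconeogenic bisphosphatase, fell by 4.00 log2 units. Respiration genes held 5 that rose and 12 that fell of 19 (adjusted p = 0.144), with ATP2, a subunit of the mitochondrial ATP synthase, at 888 against 5074 CPM. Stress response genes held 5 that rose, among them SSA3 (log2 4.09), and 9 that fell, among them GPH1 (-3.12), for an adjusted p of 0.352. In the decay machinery 9 of 23 genes rose and 3 fell (adjusted p = 0.162), or 7 and 3 adjusted over the list alone, with MOT2 at 1.53 and PAN2 at 1.21. Histone genes held 2 that rose and 1 that fell of 8 (adjusted p = 0.446). Copper response genes held 3 that fell of 5 (0.144) and G1 cyclin genes 2 of 3 (0.293), CLN1 and CLN3 by 2.83 and 1.89. XRN1 rose by 0.32 log2 units (adjusted p = 0.0381), while CCR4 (-0.10, adjusted p = 0.556) and POP2 (0.07, adjusted p = 0.698) did not pass.

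In all, 1882 of 6269 genes tested rose and 2358 fell at 5 h, and 5924 changed over the whole course. With library sizes alone 2225 rose and 1991 fell at 5 h, so which direction held more genes depended on the scaling. The median of all genes was -0.11 with TMM factors, -0.03 with RLE factors and 0.07 with library sizes alone. None of these shifts reached the size of the list medians beyond 2 log2 units.

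By 9 h the meiotic lists stood at different levels. Early genes were at a median of 3.53, with 27 that rose and 1 that fell of 30, while middle genes stood at 5.64 (33 of 33 rose) and late genes at 6.07 (16 rose and 1 fell of 17). DIT1, which makes the dityrosine of the spore wall, rose from 18.7 to 13180 CPM (log2 9.46, SE 0.80, adjusted p = 7.62e-09). SPS4 reached 28830 ± 6570 CPM from 166 ± 148 (log2 7.44). YLR012C had the largest rise among well-measured genes (log2 10.46, SE 0.91, adjusted p = 1.17e-08), followed by GAT3 (8.71) and the hexose transporter gene HXT10 (8.44). YPR077C had 1 count at 0 h and a ratio of 817 (95% interval 147 to 32300). Glycolysis remained low, with all 16 genes lower than at 0 h by the test and a median of -5.32. TDH1 fell by 8.87 log2 units, and GPM1 and PGK1 by 6.51 and 6.35, where YKL153W and YCR013C, which overlap these 2, fell by 6.38 and 6.03.

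Respiration genes also fell at 9 h, 14 of 19 (adjusted p = 5.46e-05, and adjusted p = 0.129 with an estimated correlation), with ATP2 at -3.66 and COX5A at -2.72 log2 units. Gluconeogenesis genes held 12 that fell and 1 that rose of 16 (adjusted p = 0.00114, and adjusted p = 0.129 with an estimated correlation). Ribosomal protein genes stood at a median of -1.38 with 116 of 137 lower, or 118 lower and 1 higher adjusted over the list alone (adjusted p = 0.147 with an estimated correlation). The 8 haploid-specific genes that rose of 11 included STE18, at 261 against 12.8 CPM, and MFA2, whose 2 counts at 0 h gave a ratio of 35.0 (95% interval 9.69 to 289). With an estimated correlation the adjusted p was 0.0296 for early genes, 0.147 for middle genes, 0.129 for late genes and 0.0623 for glycolysis and haploid-specific genes. The stress genes SSA3 (log2 4.74) and DDR2 (4.11) and the decapping gene DCP1 (1.21) rose. CLN1, CLN2 and CLN3, which start the mitotic cycle, all fell, CLN1 by 3.76 and CLN3 by 2.87. POP2 rose by 0.68 (adjusted p = 0.000902). CCR4 was at -0.42 (adjusted p = 0.0544) and XRN1 at 0.11 (adjusted p = 0.527). In total 1786 genes rose and 2140 fell, or 1989 and 1921 with RLE factors, and the median of all genes was -0.15 with TMM factors and -0.04 with RLE factors.

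**Figure D1:**
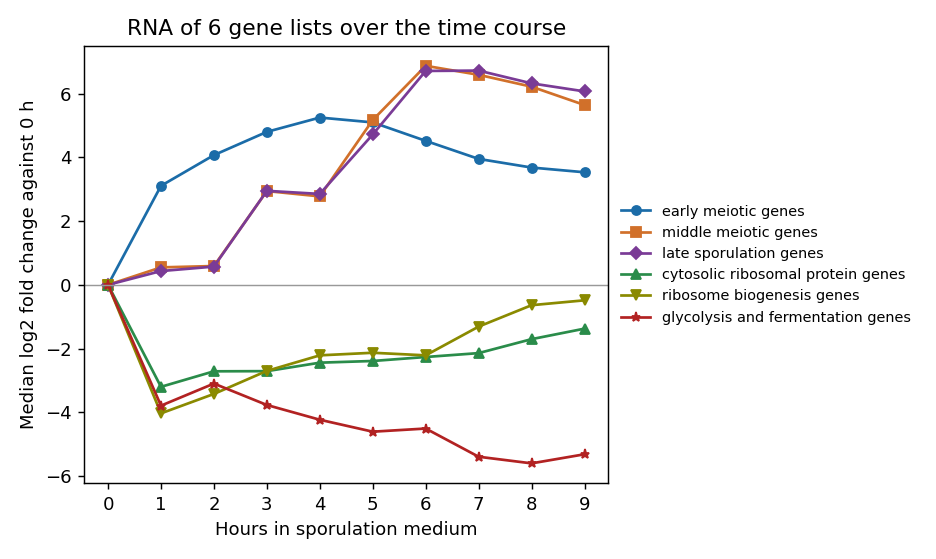
Median log2 fold change of RNA against 0 h (vertical axis) for 6 gene lists at each hour in sporulation medium (horizontal axis), from edgeR with 2 libraries per hour. Early meiotic genes stood at 3.11 at 1 h, before middle and late genes, while glycolysis genes stood at -5.32 at 9 h.

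Already at 1 h, 29 of 30 early genes rose (median 3.11), and 29 of 29 ribosome biogenesis genes fell (median -4.03), more than their median of -2.13 at 5 h, a difference that was not tested. Ribosomal protein genes stood at -3.20, with 135 of 137 lower. These 3 lists passed camera also with an estimated correlation (adjusted p = 0.00774, 0.00774 and 0.0151 in that order). All 8 histone genes fell at 1 h (median -1.30, adjusted p = 0.000117, and adjusted p = 0.125 with an estimated correlation).

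Most of the tails that changed against 0 h did so at 1 h, 5 h and 6 h, nearly all of them longer. Library medians here cover only the 244 genes with at least 20 tags in every library of the time course. The median tail of a library was 18.6 ± 2.05 nt at 0 h (n = 2), 23.6 ± 1.53 at 1 h, 22.9 ± 1.85 at 5 h, 18.5 ± 1.03 at 7 h and 18.8 ± 1.41 at 9 h. At 5 h, 52 of 559 genes tested had longer tails and 1 had a shorter tail. CWP1, a cell wall mannoprotein, went from 18.1 ± 1.28 to 31.8 ± 1.63 nt (13.7 nt, SE 2.81, adjusted p = 0.0124, limma). MBF1, a transcriptional coactivator, went from 25.6 to 37.3 nt (adjusted p = 0.00327), SDH2 of succinate dehydrogenase from 15.7 to 27.2 nt (adjusted p = 0.0165) and COX5A of cytochrome oxidase gained 10.8 nt (adjusted p = 0.0276). SHM1, serine hydroxymethyltransferase, was the gene with the shorter tail, at 18.9 against 25.3 nt (adjusted p = 0.043).

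Of 18 respiration genes measured at 5 h, 6 had longer tails, or 13 adjusted over the list alone, with a median of 6.97 nt, and COX6 gained 10.9 nt. In the gluconeogenesis list 1 of 12 had a longer tail, IDP2 (7.01 nt), or 5 adjusted over the list alone. RPS28B was the ribosomal protein gene with a longer tail (17.3 nt, adjusted p = 0.0155) of 25 measured. For ribosomal protein and stress genes the median and mean change were above 0 and the camera direction was down, and no list passed camera in tail length at 5 h or 9 h. Tails of IME1, the master regulator of meiotic entry (9.25 nt longer, adjusted p = 0.0737), XRN1 (6.24, adjusted p = 0.0913), PAB1 (6.43, adjusted p = 0.0569) and CCR4 (4.31, adjusted p = 0.247) did not pass. At 9 h, 2 of 373 genes had longer tails, YCR024C-B (33.9 against 16.6 nt, adjusted p = 9.85e-05) and DPA10 (adjusted p = 0.00405), and 4 had shorter tails, among them CAR2 (-7.31 nt, adjusted p = 0.0104) and TDH3 (12.5 against 17.8 nt, adjusted p = 0.0192). The other hours had 46 longer at 1 h, 46 longer and 4 shorter at 6 h, and from 1 to 4 changed at 2, 3, 4, 7 and 8 h. Over the course 92 of 244 genes changed in tail length.

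These tail counts rested on few libraries and on the level of whole libraries. The count at 5 h was 0 without replicate 2 at 5 h, where 53 genes changed in the full set, and with each library centred on its median it was 19 longer and 38 shorter. At 9 h centring gave 29 longer and 22 shorter. With the replicate number as a block, more tails changed at 5 h, at 9 h and over the course, so genes that did not pass here may pass there. Those counts are given with the other alternatives below.

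**Figure D2:**
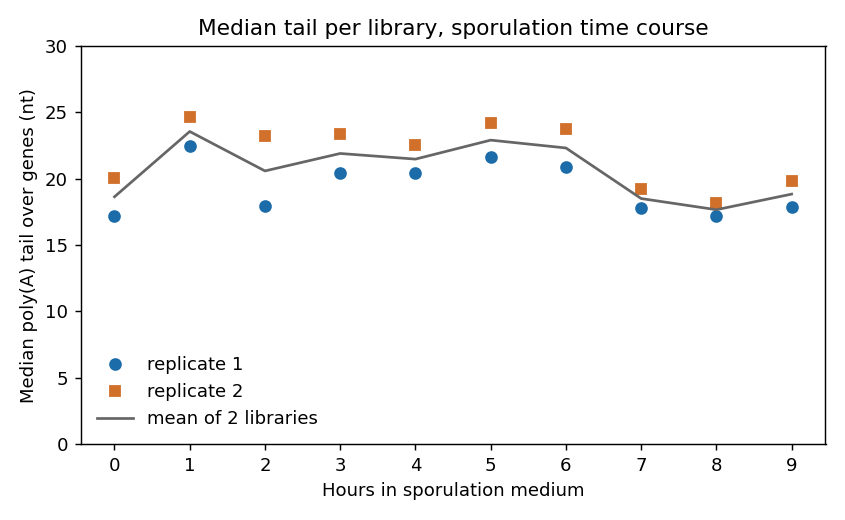
Median poly(A) tail length over genes with enough tags in every library (nt, vertical axis) at each hour in sporulation medium (horizontal axis), with 1 point per library and a line through the mean of 2. Replicate 1 lay below replicate 2 at all 10 times, and the means ran from 17.7 nt at 8 h to 23.6 nt at 1 h.

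A steady trend of median tail length with the hour did not pass over all 20 libraries (Pearson r = -0.34, permutation p = 0.142, Spearman rho = -0.32, permutation p = 0.167, 100000 resamples, two-sided). Such correlations cannot show a rise followed by a fall, and the means were 18.6 nt at 0 h, 23.6 at 1 h and 17.7 at 8 h. Without the 2 libraries at 0 h it fell with time (r = -0.60, permutation p = 0.00961, rho = -0.59, permutation p = 0.0113), and without those at 9 h r was -0.26, so the relation rested on which end was included. Within replicate number 1 r was -0.27 and within number 2 -0.51. Median tail and the number of tags had r = 0.50 (unadjusted permutation p = 0.027, rho = 0.49, unadjusted permutation p = 0.0317, n = 20), a relation chosen after the data were seen and the other member of this family of 2, over which it was not adjusted. Without the 2 libraries farthest in tags r was 0.58 (permutation p = 0.013, rho = 0.54, permutation p = 0.0212). Within replicate number 1 r was 0.49 (permutation p = 0.151, rho = 0.39) and within number 2 -0.28 (permutation p = 0.434, rho = -0.41). Replicate 1 had the shorter median tail and fewer tags at 10 of 10 times, so depth and replicate number cannot be told apart.

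Changes in tag counts followed changes in RNA-seq across genes, at Spearman rho between 0.556 and 0.903 over the main comparisons. Correlations across genes, here and later, are not over independent replicates. The change in tail length was related to the change in RNA at rho = 0.26 at both 5 h and 9 h, and to the change in tag counts at -0.02 and -0.06.

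Return to growth asks how cells put in SPO for 1 h or 7 h respond when nutrients come back. Meiosis can be left up to a point in prophase, and on which side of it these cultures stood was not measured. After 20 min in YPD from 1 h in SPO, genes of ribosomes rose while early meiotic and gluconeogenesis genes fell. All 137 ribosomal protein genes rose, with a median of 6.79 log2 units, and all 29 ribosome biogenesis genes rose, with a median of 7.82. NSR1, a nucleolar protein of ribosome assembly, went from 3.29 ± 3.44 to 3348 ± 70.1 CPM (log2 9.77, SE 0.30, adjusted p = 4.52e-28, edgeR), and RPL21A from 2.71 ± 0.208 to 1917 ± 44.4 CPM. IME1 fell by 8.04 log2 units to 2.79 CPM, and DMC1, the meiotic recombinase, from 984 to 3.62 CPM, among 28 early genes that fell and 1 that rose of 29 (adjusted p = 0.0722 with an estimated correlation). ACS1, the acetyl-CoA synthetase used for acetate, fell from 14940 ± 1720 to 23.6 ± 1.20 CPM, and all 16 genes of its list fell, with a median of -7.23 (adjusted p = 0.074 with an estimated correlation).

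The glucose-phosphorylating gene HXK2 rose from 5.42 to 378 CPM and PDC1 from 215 to 4304 CPM, but the glycolysis list held 6 that rose and 7 that fell. RGI2, a gene of respiratory metabolism, fell by 9.95, SPG1 by 9.59 and the acetate transporter gene ADY2 by 8.99 log2 units. PHO92, a reader of methylated mRNA in meiosis, had 0 counts at 20 min and was at least 306-fold lower, from 168 ± 20.1 CPM. RRP3 had 1 count before transfer and a ratio of 975 (95% interval 175 to 38500), and LEE1 had 1 count at 20 min and was lower by a ratio of 944 (95% interval 170 to 37300). YGR160W, which overlaps NSR1, rose by 9.70. All 19 stress genes fell (median -4.46), DDR2 to 7.95 from 1750 CPM. The poly(A)-binding protein gene PAB1 rose to 2725 from 311 CPM among 12 decay machinery genes that rose and 6 that fell of 23. CCR4 rose by 0.93 (adjusted p = 7.94e-07) and POP2 by 0.52 (adjusted p = 0.00566), while XRN1 fell by 1.12 (adjusted p = 1.04e-08). CLN3 rose to 295 from 29.5 CPM, RME1, a repressor of meiosis, was at least 36.7-fold lower, and 7 of 8 histone genes fell (adjusted p = 0.00696, and adjusted p = 0.169 with an estimated correlation).

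Ribosomal protein and ribosome biogenesis genes passed camera also at adjusted p = 0.0413 with an estimated correlation. Early genes (adjusted p = 9.94e-10) were at 0.0722 with an estimated correlation, and gluconeogenesis (2.64e-10), stress (9.13e-09) and late genes (0.00957) at an adjusted p of 0.074 with an estimated correlation. Middle genes (3 rose, 17 fell of 33) passed at 0.0399 and not with an estimated correlation (adjusted p = 0.371 with an estimated correlation). Of 6109 genes 2345 rose and 2611 fell. Fitted on the 4 libraries alone 2553 rose and 2488 fell. With library sizes alone the split was 1656 to 3430, and the median of all genes moved from -0.10 to -0.77. The lists with medians beyond 4 kept their direction relative to that shift. For respiration genes the median was 0.16, the mean -0.83 and the camera direction down (adjusted p = 0.337).

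At 5 min the same lists were on the way. Ribosomal protein genes rose (136 of 137, median 4.37) and so did all 29 ribosome biogenesis genes (median 6.27), both at adjusted p = 0.0219 with an estimated correlation. NSR1 was at 2255 against 3.29 CPM, and RRP3 at a ratio of 538 (95% interval 96.5 to 21200). All 29 early genes fell (median -2.32, adjusted p = 0.104 with an estimated correlation), IME1 by 3.64 log2 units. All 16 gluconeogenesis genes fell, at adjusted p = 0.218 with an estimated correlation, CIT2 to 238 from 7471 CPM. RGI2 fell to 19.1 from 3420 CPM. In all 1671 genes rose and 2855 fell, and the median of all genes was -0.43, or -0.26 with RLE factors. Fitted on the 4 libraries alone 2073 rose and 1862 fell, so which direction held more genes depended on the libraries fitted.

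Tails of ribosomal protein mRNAs lengthened within 5 min of transfer from 1 h in SPO. Of 75 such genes measured 72 had longer tails, or 73 adjusted over the list alone, with a median gain of 22.7 nt (adjusted p = 6.5e-45, limma camera, and adjusted p = 0.111 with an estimated correlation). RPS11A went from 16.4 ± 1.32 to 56.0 ± 6.95 nt (39.7 nt longer, adjusted p = 1.01e-07), RPL14A from 22.5 to 52.8 nt and NOG1, a nucleolar GTPase of ribosome assembly, from 22.9 to 56.3 nt (adjusted p = 1.51e-07). Early meiotic genes shortened in 6 of 10 cases, or 8 adjusted over the list alone, with HOP1 of the chromosome axis at -13.6 and SPO22 at -12.3 nt. Gluconeogenesis genes shortened in 6 of 15 cases, or 10 adjusted over the list alone (median -5.87 nt, adjusted p = 1.57e-06, and adjusted p = 0.309 with an estimated correlation), CIT2 by -9.14 and JEN1 by -8.73 nt.

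At 5 min TMA10 (-13.2 nt), IRR1 (-12.4) and PRM4 (-11.6) also had shorter tails, and PAB1 had a longer one, at 40.9 against 26.2 nt (adjusted p = 8.06e-05). In the respiration and stress lists, camera passed downward (adjusted p = 0.00106 and 0.016) and was at adjusted p = 0.509 with an estimated correlation for both. The change in tail was related to the change in RNA across genes at rho = 0.78, and to the change in tag counts at 0.48. In all 227 of 2046 genes had longer and 73 shorter tails. Centred on library medians the split was 262 to 212, and without replicate 1 at 5 min 173 tails changed in place of 300.

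At 20 min the median gain of ribosomal protein tails was smaller than at 5 min, a difference that was not tested. They were longer than before transfer in 52 of 75 genes, or 64 adjusted over the list alone, with a median of 10.3 nt (adjusted p = 1.04e-09, and adjusted p = 0.506 with an estimated correlation). RPS11A stood at 38.5 nt and NOG1 at 3.89 nt above its start (adjusted p = 0.287). FIT3, a cell wall protein of iron retention, went from 20.4 to 42.5 nt (adjusted p = 9.65e-06), and RPS22B, MSS116 and SDS23 gained 17.9, 17.3 and 16.9 nt. DMC1 fell from 32.0 ± 0.725 to 13.7 ± 0.855 nt (adjusted p = 9.39e-05), the translational repressor gene RIM4 from 27.2 to 13.1 nt, JEN1 by 13.5 nt and HED1 by 11.3 nt. Of 10 gluconeogenesis genes 6 were shorter, or 8 adjusted over the list alone (median -7.67 nt, adjusted p = 3.78e-10, and adjusted p = 0.259 with an estimated correlation). Of 7 stress genes 3 were shorter, with DDR2 at -10.4 nt (adjusted p = 8.41e-05, and adjusted p = 0.291 with an estimated correlation), and 4 of 19 respiration genes were longer, or 3 adjusted over the list alone. XRN1 had a longer tail (10.2 nt, adjusted p = 0.0192), and CCR4 (3.31 nt, adjusted p = 0.349) and POP2 (adjusted p = 0.357) did not pass.

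In all 287 of 1411 genes had longer and 84 shorter tails at 20 min, and centred on library medians the split was 154 to 206. The median tail of a library was 24.9 ± 0.396 nt before transfer, 25.7 ± 1.51 at 5 min and 28.5 ± 1.59 at 20 min. These medians cover the 1229 genes with at least 20 tags in every library of the return to growth. The count of 371 was 105 without replicate 1 at 20 min.

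**Figure D3:**
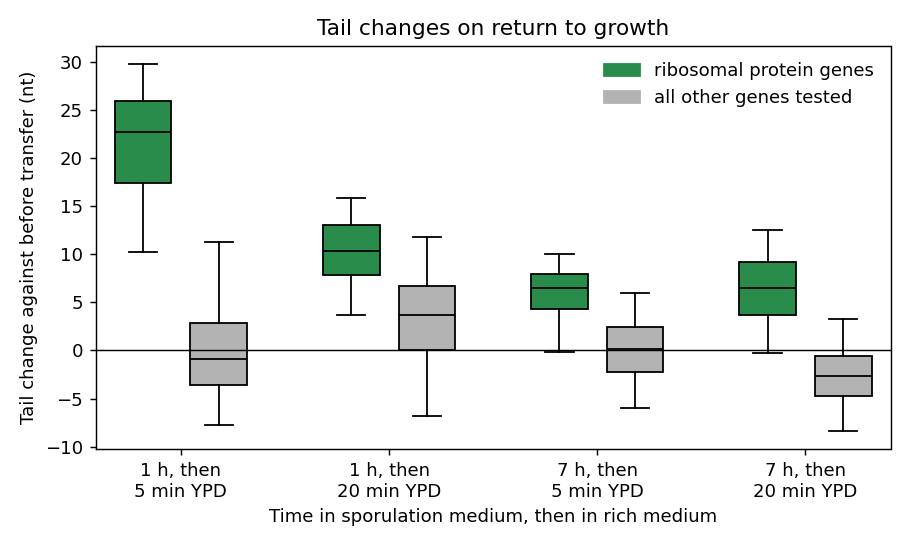
Change of mean poly(A) tail length against before transfer (nt, vertical axis) for ribosomal protein genes and all other genes tested, at 4 combinations of time in sporulation medium and in YPD (horizontal axis). Boxes span the quartiles over genes with the median as a line and whiskers reach the 5th and 95th percentiles, and the ribosomal protein median is 22.7 nt in the first group and 6.54 nt in the last.

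From 7 h in SPO the test called fewer genes after the same transfer, with 1095 that rose and 685 that fell of 6109 at 20 min. Its power was also lower, as simulated 2-fold changes were recovered in 46.3% of genes against 86.6% from 1 h. Ribosomal protein genes rose in 132 of 137 cases, or 134 adjusted over the list alone, with a median of 2.19, and ribosome biogenesis genes in 29 of 29 with a median of 2.41, both at adjusted p = 0.0258 with an estimated correlation. The stress response list held 3 that rose and 3 that fell of 19 (adjusted p = 0.512). TRR1, cytosolic thioredoxin reductase, went from 61.5 ± 14.1 to 3135 ± 144 CPM (log2 5.84, adjusted p = 1.23e-20), OYE3 from 13.4 to 394, the peroxidase gene GPX2 from 17.9 to 714 CPM, and GRE2 had 3 counts before and a ratio of 176 (95% interval 60.4 to 856). YOL150C, which overlaps GRE2, had 1 count before and a ratio of 301 (95% interval 53.9 to 11900). Early genes fell in 25 of 29 cases, at adjusted p = 0.0347 with an estimated correlation, MSH4 to 39.9 from 181 CPM.

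Middle genes fell in 23 of 33 cases at 20 min, or 25 adjusted over the list alone (adjusted p = 2.66e-06, and adjusted p = 0.113 with an estimated correlation). Late genes held 11 that fell and 3 that rose of 17 (adjusted p = 0.0355, and adjusted p = 0.13 with an estimated correlation), and DIT1 rose to 4691 from 2560 CPM. Gluconeogenesis genes fell in 9 of 16 cases, or 10 adjusted over the list alone (adjusted p = 2.75e-06, and adjusted p = 0.193 with an estimated correlation), with CIT2 at 347 against 1845 and ACS1 at 799 against 3620 CPM. Respiration genes held 12 that fell and 1 that rose of 19 (adjusted p = 1.05e-05, and adjusted p = 0.214 with an estimated correlation), or 15 and 1 adjusted over the list alone. Histone genes held 2 that fell of 8 (adjusted p = 0.0196), or 4 adjusted over the list alone, and were at adjusted p = 0.214 with an estimated correlation. RPS22A rose to 90.8 from 7.94 CPM and the RNA polymerase I gene RPA135 by 3.53 log2 units. CCR4, XRN1 and POP2 did not pass (log2 0.01, -0.06 and -0.13, adjusted p = 0.992, 0.879 and 0.766).

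At 5 min from 7 h, 1601 genes rose and 1414 fell, against 1386 and 1661 with RLE factors and 1139 and 1289 with DESeq2, and 5 lists passed camera with both correlations. Ribosomal protein genes rose in 136 of 137 cases (median 3.78), ribosome biogenesis genes in 29 of 29 (3.13), and early, middle and late genes fell in 29 of 29, 32 of 33 and 14 of 17 cases, all at adjusted p = 0.0174 with an estimated correlation. DMC1 fell to 22.2 from 449 CPM, and the cyclin gene CLB1 by 2.10 log2 units. RPS22A rose to 460 from 7.94 CPM, and CCR4 rose by 1.04 (adjusted p = 0.000222). Gluconeogenesis (12 of 16 fell), histone (7 of 8) and respiration genes (6 of 19) also passed at the preset value, with adjusted p = 0.128, 0.102 and 0.494 with an estimated correlation. The count of changed genes fell to 1627 at 5 min and 770 at 20 min without replicate 1 before transfer, which leaves the shallowest library as the start. The median of all genes at 5 min was 0.02, or -0.12 with RLE factors.

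Few tails passed the test after transfer from 7 h, where at 20 min simulated changes of 6 nt were recovered in 4.48% of genes and of 12 nt in 45.5%, so smaller shifts would mostly be missed. At 5 min limma found 0 of 2713 genes changed, where 228 had an unadjusted p under 0.05. With each library centred on its median, limma found 34 longer and 17 shorter. The 108 ribosomal protein genes measured had a median difference of 6.44 nt (43 longer and 1 shorter adjusted over the list alone). Camera, over those with a value in every library of the experiment, gave adjusted p = 3.47e-19, and adjusted p = 0.588 with an estimated correlation. At 20 min 8 of 2559 genes had longer tails, and 6 of these were ribosomal protein genes, among them RPL8B (14.1 nt), RPL5 (32.8 against 20.3 nt, adjusted p = 0.00562) and RPL2B (12.3 nt). The other 2 were the RNA helicase gene DBP2 (45.7 against 27.6 nt, adjusted p = 0.0111) and TRR1 (40.8 against 23.1 nt, adjusted p = 0.00509). Adjusted over the list alone, 46 of 107 ribosomal protein genes were longer (median 6.54 nt, camera adjusted p = 3.88e-44, and adjusted p = 0.116 with an estimated correlation) and 6 gluconeogenesis genes were shorter, with ACS1 at -5.75 nt (adjusted p = 0.0502 over all genes). Over the same 1229 genes as from 1 h, the median tail of a library was 23.0 ± 1.95 nt before transfer and 21.0 ± 1.58 at 20 min. Centred on library medians the split at 20 min was 78 longer and 5 shorter. The count was 0 without replicate 2 at 20 min and 62 without replicate 1.

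The difference between the 20 min effects at 7 h and 1 h was tested itself. It passed for 3718 genes in RNA, with 1982 higher and 1736 lower after 7 h, and with library sizes alone for 2808 higher and 1137 lower. Ribosomal protein genes rose less after 7 h in 136 of 137 cases (median difference -4.51) and ribosome biogenesis genes in 29 of 29 (-5.34), both at adjusted p = 0.035 with an estimated correlation. Genes that fell after 1 h fell less after 7 h, in 16 of 16 gluconeogenesis genes (6.07), 18 of 19 stress genes (4.34, both at adjusted p = 0.0808 with an estimated correlation) and 26 of 29 early genes (3.45, adjusted p = 0.0831 with an estimated correlation). Histone genes differed in 6 of 8 cases (adjusted p = 0.0234, and adjusted p = 0.227 with an estimated correlation). In tail length the difference passed for 89 of 1261 genes, 8 higher and 81 lower. Centred on library medians it passed for 129 higher and 34 lower, so its direction followed the level of whole libraries. Without replicate 1 or 2 before transfer at 1 h, 2 and 1 genes passed. For ribosomal protein genes, 6 of 74 differed downward with a median of -4.01 nt while the camera direction was up (adjusted p = 0.198).

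The decay mutants ask how the deadenylases and the exonuclease shape tails and RNA at each stage. In vegetative growth the median tail was longer without CCR4 (49.6 against 37.6 nt in wild type) and without POP2 (42.2 nt), and shorter without XRN1 (23.3 nt), over 4385 genes. Loss of CCR4 went with longer tails in 98.9% of genes, and 82.6% of genes were longer by more than the yardstick. Without XRN1, 98.1% of genes had shorter tails and 81.5% were shorter beyond the yardstick. In premeiotic cells the differences from wild type were 8.53 nt without CCR4, 4.96 nt without POP2 and -13.7 nt without XRN1. In the libraries labelled meiotic, from 5 h in SPO, they were 0.443 nt, -0.417 nt and -17.7 nt. There middle meiotic genes stood 111-fold, 99.1-fold and 57.9-fold below wild type by median, with counts under 3 set to 3. Stage of the culture and loss of each gene can therefore not be told apart at that time. Weighted by tags, the difference without XRN1 was -4.11 nt in vegetative growth, and those without CCR4 and POP2 in meiosis were -2.37 and -3.00 nt. Each group had 1 library, so these values carry no replicate check. The highest mean tail of any gene was 140, 108 and 103 nt in vegetative, premeiotic and meiotic wild type. In the deletion libraries it ran from 78 to 99 nt, so the measured range differed between wild type and the mutants.

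The targeted genes were read first. CCR4 had 0 RNA-seq counts in the deletion in vegetative growth and meiosis, at least 61.1-fold and 15.0-fold lower than wild type, and 1 count in premeiotic cells. POP2 had 0 counts at the 3 stages, at least 27.1-fold, 15.0-fold and 6.03-fold lower. XRN1 had 2, 1 and 1 counts in its deletion, or 2.71, 1.76 and 4.32 CPM against 373, 151 and 266 in wild type. Poly(A) tags were still assigned to each deleted gene (CCR4 6, 74 and 30, POP2 55, 62 and 23, XRN1 12, 19 and 8 tags), but 3' tags can lie outside the deleted part and check nothing.

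**Figure D4:**
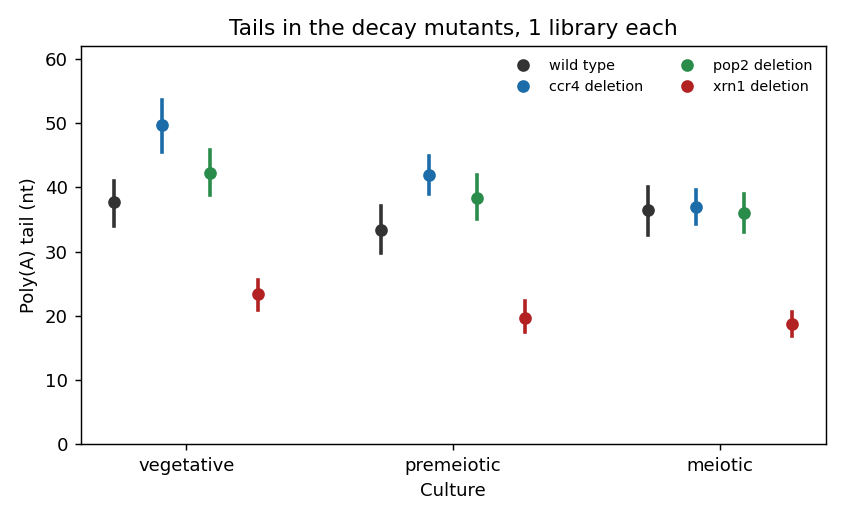
Poly(A) tail length (nt, vertical axis) in wild type and 3 deletion strains at each stage (horizontal axis), with the median over 4385 genes as a point and the quartiles over genes as a line, 1 library each. The vegetative ccr4 deletion lies at 49.6 nt, and all 3 xrn1 deletion libraries lie at or below 23.3 nt.

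Named genes and lists moved apart within these shifts. In vegetative growth GIC1, a Cdc42 effector, had a tail of 68.0 nt without CCR4 against 30.6 nt and was also 27.2 nt longer without POP2, and SEF1 and IRE1 were longer in both strains. The ribosomal protein list stayed near wild type without XRN1, at a median of -0.541 nt against -9.04 nt in matched random lists of other genes (percentile 100), with RPL43A longer by 3.62 nt, while early meiotic genes stood at -30.6 nt (percentile 0). Early meiotic mRNA was scarce in these libraries. Of 25 early genes in the RNA comparison, 17 had over 3 counts in at least 1 of the libraries compared. Histone tails were 14.7 nt longer without CCR4 (percentile 99.8).

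Premeiotic ribosomal protein tails went against the rest of the transcripts. Their median difference from wild type was -6.01 nt without CCR4 (128 of 135 shorter) and -12.2 nt without POP2 (133 of 135 shorter), both at percentile 0, where random lists of other genes matched on abundance stood at 8.59 and 4.89 nt. RPL2A was at 31.4 nt without CCR4 against 44.5 nt, and RPS21B at 32.9 nt without POP2 against 53.8 nt. In wild type the same list was 13.7 nt longer in premeiotic than in vegetative cells (percentile 100). That comparison of stages within wild type was chosen after the data were seen. All differences in this paragraph share 1 wild-type premeiotic library, which had the fewest tags of the experiment (1715150). They cannot be told apart from a deviation of that library. Premeiotic stress genes were 15.3 nt longer without CCR4 (percentile 100) and 11.4 nt without POP2 (percentile 99.95), and SUR1 reached 57.6 nt without CCR4 against 22.4 nt. Without XRN1 the hexose transporter gene HXT7 had a tail of 52.0 nt in premeiotic cells against 21.1 nt, while glycolysis genes stood at -0.673 nt (percentile 100).

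In the libraries from 5 h in SPO the mutants held little RNA of the middle and late lists. MEC1, the checkpoint kinase, had longer tails there without CCR4 (25.8 nt) and POP2 (26.6 nt), and SOL1 shorter ones (-25.4 and -25.6 nt). Without XRN1, SOL1 was at 22.6 against 64.1 nt. Ribosomal protein genes stood at -5.42 nt without POP2 (percentile 0) and ribosome biogenesis genes at -2.98 nt without CCR4 (percentile 0.21).

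RNA of ribosomal protein genes was lower in vegetative mutants, and that of gluconeogenesis and stress genes higher. Ribosomal protein genes had median log2 differences of -0.53 without CCR4, -1.01 without POP2 and -1.34 without XRN1, each at percentile 0. Matched random lists of other genes stood at -0.15, -0.20 and -0.54. Gluconeogenesis genes were higher by 2.05, 2.98 and 1.20 and stress genes by 1.00, 1.45 and 0.84, each at percentile 100. HSP12 was at 1051 CPM without POP2 against 26.2, and the iron uptake genes FET3 and SIT1 at 1460 against 61.2 and 1258 against 76.1 CPM without CCR4. FLO11, a cell surface flocculin, was at 88.1 CPM without XRN1 against 7577. The tail and RNA differences were related across genes at rho = -0.451 without XRN1, against 0.0463 without CCR4 and 0.0219 without POP2. With tags as the measure of abundance these relations were -0.671, -0.148 and -0.106, so the last 2 turned sign.

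In premeiotic cells ribosome biogenesis genes were lower without CCR4 (-1.93) and POP2 (-1.91, percentile 0), and glycolysis genes higher (1.63 and 1.44). IME1 was at 534 CPM without CCR4 against 3032, and ADY2 at 795 against 6259. Ribosomal protein genes were higher without XRN1, by 1.59 (percentile 100).

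At 5 h in SPO the meiotic lists were lower than in wild type in all 3 mutants, with early genes least so without XRN1. Middle genes stood at a median log2 difference of -6.58, -6.58 and -5.80 without CCR4, POP2 and XRN1, and late genes at -7.08, -7.12 and -6.28, each at percentile 0. With no prior count and counts under 3 set to a floor of 3, the medians were -6.79, -6.63 and -5.86 for middle genes. For late genes they were then -7.20, -7.23 and -6.05. Early genes stood at -5.30, -3.86 and -1.77, or -5.41, -4.02 and -1.79 with that floor. SPS4 had 3 counts (6.70 CPM) without CCR4 against 21660 CPM, SPR3 was at least 580-fold lower without POP2, LDS1 at least 391-fold lower without CCR4 and SPO19 at least 411-fold lower without XRN1. Glycolysis genes were higher by 3.08 without CCR4 and 3.61 without POP2, and the ammonium transporter gene MEP2 stood at 5387 against 91.0 CPM without CCR4. In wild type, middle genes were 7.47 higher in meiosis than in vegetative growth (7.94 with the floor) and ribosomal protein genes -5.07.

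Across genes within a library, longer tails went with lower abundance in vegetative wild type (rho = -0.424), and this relation was 0.11 without XRN1. In premeiotic and meiotic wild type it was -0.0466 and -0.0144. The median rho over libraries was 0.118 in the time course (-0.125 to 0.342) and 0.17 in the return to growth (-0.0241 to 0.322), or 0.0254 and 0.0626 with tags as abundance.

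The 3 libraries fragmented before ligation ask whether the comparisons hold in RNA-seq made by that order of steps. For meiotic against vegetative wild type the log2 differences were related to those of the other RNA-seq libraries at rho = 0.938 across 2191 genes. For the xrn1 deletion against wild type rho was 0.694 across 2573 genes. Genes under a minimum of 20 counts were left out. The early, middle and late lists were not placed in these libraries, so as lists they were not checked here. The glycolytic gene ENO2 was at 94.5 CPM in meiosis against 21930, and GSC2, a spore wall glucan synthase, at 8091 against 120 CPM. The 105 ribosomal protein genes over the minimum were at a median of -5.20. Without XRN1, FLO11 was at 177 against 14300 CPM, ribosomal protein genes were at -1.91 and XRN1 had 0 counts. The median over genes was -0.49 and -0.40 in these comparisons, and total counts ran from 434140 to 854952. The deposited 3' bias ratio had medians between 0.881 and 0.991.

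The degron experiment asks what follows within minutes of losing Xrn1. Here 500 µM auxin and 50 µM copper sulfate were added together. The median tail was 39.7 nt in the wild-type control, 38.0 nt in the degron strain at 0 min and 26.1 nt at 30 min, over 4286 genes. Between 0 and 30 min 98.3% of genes were shorter, 69.7% beyond the yardstick, and weighted by tags the difference was -4.42 nt. XRN1 stood at 230, 128 and 122 CPM, and the degron acts on the protein, so RNA does not check the depletion. No wild type was given copper, so copper and time after induction coincide.

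Ribosomal protein tails were at a median of -2.59 nt between 0 and 30 min (percentile 99.83), against -12.0 nt over all genes and -5.25 nt in matched random lists of other genes, and stress genes at -4.42 nt (percentile 99.98), with HSP12 longer by 8.44 nt. The metallothionein gene CUP1-2, a target of copper, stood at 35.3 CPM in the control, 187 at 0 min and 2669 at 30 min, and its tail at 38.1, 66.7 and 29.8 nt. Stress genes were higher at 30 min by 1.75 log2 units (percentile 100), with the disaggregase HSP104 at 737 against 48.8 CPM and SSA1 at 2398 against 249. The copper transporter gene CTR1 went from 373 to 80.1 CPM and the iron transporter gene SIT1 from 1014 to 59.1 CPM, where SIT1 was at 57.2 CPM in the control. At 0 min the degron strain already differed from the control, with gluconeogenesis genes higher by 1.11 (percentile 100) and FET3 at 986 against 119 CPM.

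**Figure D5:**
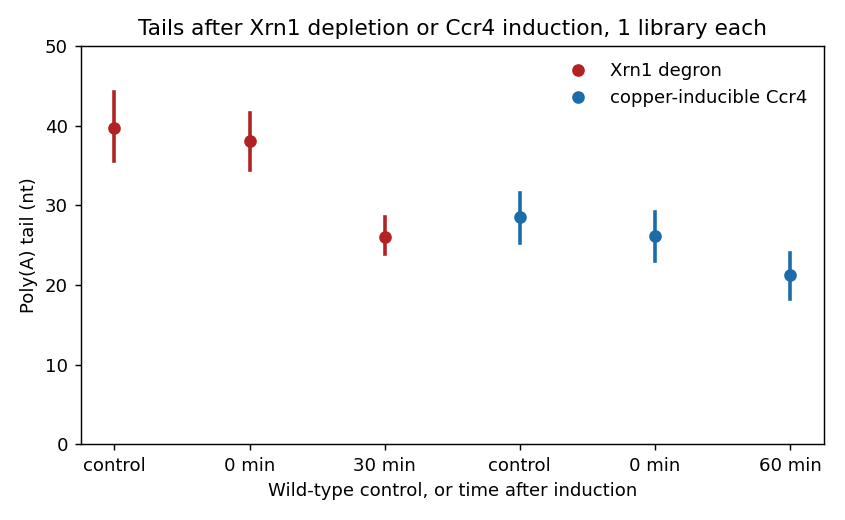
Poly(A) tail length (nt, vertical axis) in the Xrn1 degron and copper-inducible Ccr4 experiments, for the wild-type control and the times after induction (horizontal axis), with the median over genes as a point and the quartiles as a line, 1 library each. The degron median went from 38.0 to 26.1 nt and the Ccr4 median from 26.1 to 21.3 nt.

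The Ccr4 experiment asks whether more of this deadenylase shortens tails. After 60 min of 50 µM copper sulfate CCR4 stood at 490 CPM, against 105 at 0 min and 141 in the wild-type control. The median tail over 2179 genes was 28.5 nt in the control, 26.1 nt at 0 min and 21.3 nt at 60 min. From 0 to 60 min 90.6% of genes were shorter, 13.3% beyond the yardstick. All 16 glycolysis genes were shorter, with a median of -8.01 nt (percentile 0), GPM1 by -11.0 and ENO1 by -10.6 nt, and all 8 histone genes by a median of -3.90 nt (percentile 98.94). CAM1, SIM1 and SSA1 were at -12.3, -12.3 and -12.1 nt, and CHD1 at 2.43 nt.

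In RNA, all 137 ribosomal protein genes were lower at 60 min than at 0 min, with a median of -1.02 (percentile 0). Random lists of other genes matched on abundance stood at -0.56. CUP1-2 stood at 30.7, 31.2 and 405 CPM in the control, at 0 min and at 60 min, and CTR1 at 388, 483 and 55.6 CPM. HSP12 was at 194 CPM at 60 min against 56.8 at 0 min, and the arginine synthesis gene ARG1 at 163 against 900 CPM. XRN1 stood at 274, 263 and 259 CPM. As in the degron experiment, copper and time after induction coincide. The highest mean tail of any gene was 61 nt in each of these 3 libraries against 99 nt in the degron experiment, so measured tails spanned a narrower range.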

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

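Of the tests weighed here, those on genes with shorter tails, on mRNA raised in general, on the measurable range, on tag counts, on the stage of the cultures, on the Ccr4 strain alone and on shifts before induction were chosen only after the result was seen. The response to 20 min in YPD was flagged because it differed between cells from 7 h and 1 h in SPO by a test of the difference itself. That difference passed for 3718 genes in RNA and for 89 in tail length. The second count was 1 to 17 with any of 5 libraries left out and rose to 153 without another, and the direction of these calls turned from 81 lower and 8 higher to 34 lower and 129 higher when libraries were centred on their medians.

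The longer ribosomal protein tails 5 min after transfer from 1 h in SPO were weighed against 3 explanations. Reads shared between gene copies would leave single-copy genes out, but their median change was 24.8 nt (n = 13) against 22.3 nt for duplicated ones (n = 62), which argues against it. A shift of whole libraries would end most calls on centring, but the 72 of 75 genes called longer were the same 72 before and after. Other genes raised at least 4-fold gained 13.4 nt more than genes whose RNA stayed nearly level (79 and 316 genes). Only ribosomal protein genes were left out there, so ribosome biogenesis genes, which also rose, could be among the 79. The comparison also restates the relation of tail change to RNA change across genes (rho = 0.78) and is no separate support. That long tails here mark newly made mRNA stays a hypothesis, and newly made and older mRNA were not measured apart.

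The small difference in meiotic tails without CCR4 or POP2 was weighed in the same way. A ceiling on measurable tails would hold the meiotic ccr4 library near its vegetative level, but its upper quartile lay at -13.9 nt relative to it. That quartile restates the lower median of this library (36.9 against 49.6 nt) and is no separate test. It shows only that longer tails could be measured in the same strain. Low tag counts would lift the difference under a stricter minimum, but it was 0.475 nt with at least 50 tags. Middle meiotic genes stood at -6.58 log2 units in that library, so stage of the culture and loss of Ccr4 cannot be told apart. No biological explanation was tested beyond this.

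Tail shortening in the degron strain could come from the copper given with auxin. Its profile across genes followed the xrn1 deletion, which had no copper, more than the Ccr4 induction, which did. The difference in rho was 0.939 (0.736 against -0.203, 95% bootstrap interval 0.892 to 0.986 over 2544 genes). That interval resamples genes of single libraries and does not cover variation between cultures. The Ccr4 induction also added Ccr4 and was sampled at 60 min, so a low rho with it cannot exclude a copper effect. The profile resembled loss of Xrn1 without copper, and no more is shown. The highest mean tail was 61 nt in the Ccr4 libraries and 99 nt in the degron libraries, and over the 1272 genes with the shorter tails before Ccr4 induction rho was 0.775 against -0.475. For the Ccr4 strain the question stays open as well. The degron strain, with copper and no added Ccr4, also shortened (-12.0 nt), and no wild type was given copper. Shifts present before induction came to 14.2% of the shift after it in the degron strain and 51.0% in the Ccr4 strain, so in the latter, with 1 library each, a difference between libraries cannot be told apart either.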

How the results depend on the processing

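Of the tests used here, those with library sizes alone, a robust edgeR prior, centring and block together, a single replicate number random lists without the list's own members and genes with shorter tails were chosen only after the result was seen. Over 86 results, 168 other alternatives stayed within the limits set for them, 78 moved, 8 reversed and 1 passed where the main value did not. Of the libraries left out, 75 settings stayed within 1.5 times and 29 moved. Where no cause is given, the cause was not tested. With its own members left out of the random lists, 204 of 205 list medians outside the percentiles named stayed outside, and 12 more came outside. A library alone in its group was assumed to vary like the others.

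With at least 2-fold change required, RNA counts were 2565 at 5 h, 2538 at 9 h, and 2003 and 1041 at 5 and 20 min from 7 h, as that filter removes small changes. For tails, a tag minimum of 10 gave 34 at 5 h, 1 at 5 min from 7 h and 42 for the difference of responses. A minimum of 50 gave 3 at 9 h, 44 over the course, 183 and 242 at 5 and 20 min from 1 h, and 8 and 14 from 7 h. With log2 tails the counts were 35 at 5 h and 34 and 53 from 7 h. Centred libraries gave 51 at 9 h, 474 at 5 min from 1 h, 51 and 83 from 7 h and 163 for the difference of responses. Weights by tags gave 3 at 20 min from 7 h and 135 for the difference.

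Replicates share only a number, and pairs deviated together above 0.1 in 22 of 45 cases for RNA and 19 of 45 for tails in the time course, and in 0 of 15 for each in the return to growth. With the replicate number as a block, tail counts were 212 at 5 h, 47 at 9 h, 204 over the course, 5 at 20 min from 7 h and 39 for the difference, and no other count moved by over 1.5 times. Centred and with block they were 85, 54, 33 at 5 min from 7 h, 78 at 20 min and 158 for the difference.

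With libraries left out in turn, RNA counts ran from 3531 to 3904 at 5 h, 3001 to 3627 at 9 h, 5853 to 5988 over the course, 4125 to 4325 and 4605 to 4773 at 5 and 20 min from 1 h, and 2560 to 3649 for the difference. They ran from 1627 to 2890 and 770 to 1626 at 5 and 20 min from 7 h, both lowest without replicate 1 before transfer. Tail counts at 5 h ran from 0 (without 5 h replicate 2) to 40, with 2 without 0 h replicate 1 and 25 without 5 h replicate 1. At 9 h they ran from 1 (without 9 h replicate 1) to 6, with 3 without 0 h replicate 2. Over the course they ran from 37 (8 h replicate 1) to 165 (2 h replicate 2), with 41, 46, 56, 57, 61 and 164 without 7 h replicate 1, 1 h replicate 2, 9 h replicate 1, 8 h replicate 2, 5 h replicate 2 and 2 h replicate 1. From 1 h they ran from 173 (without replicate 1 at 5 min) to 264 at 5 min and 105 (replicate 1 at 20 min) to 399 at 20 min, with 152 and 160 without replicates 1 and 2 before transfer. From 7 h they ran from 0 to 3 (replicate 1 before transfer) at 5 min, and from 0 (replicate 2 at 20 min) to 62 (replicate 1 at 20 min) at 20 min, with 4 without replicate 2 before transfer. For the difference they ran from 1 (1 h before transfer, replicate 2) to 153 (1 h, 20 min, replicate 2), with 2, 4, 9 and 17 without replicate 1 before transfer at 1 h, replicate 2 before transfer at 7 h and replicate 1 at 20 min from 1 h and from 7 h.

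Weighted by tags, the median tail difference was 6.76 nt at 20 min from 1 h (main 3.59), -4.11 and -10.8 nt without XRN1 in vegetative and premeiotic cells, -2.37 and -3.00 nt without CCR4 and POP2 in meiosis, and -4.43 and -4.42 nt in the degron strain at 30 min against control and 0 min. The relation of tail to abundance was 0.0254 and 0.0626 with tags as abundance in the first 2 experiments, 0.218 and -0.447 with a minimum of 50 tags in the return to growth and the Ccr4 experiment, and -0.245 in the latter without ribosomal protein genes. That of tail change to RNA change, with 50 tags, was 0.379 at 5 h, 0.353 at 9 h, 0.686 at 20 min from 1 h, 0.483 and 0.465 from 7 h and 0.528 for the difference. With tags as abundance it reversed to -0.0247 at 5 h and -0.0555 at 9 h, and was 0.48 and 0.416 from 1 h, 0.311 and 0.244 from 7 h and 0.125 for the difference. It also reversed without CCR4 and POP2 in premeiotic cells (-0.0858, -0.164), in all 3 meiotic mutants (-0.0194, -0.0171, -0.043) and between 0 and 60 min of Ccr4 induction (-0.0823). Relations near 0 also turned sign, without CCR4 and POP2 in vegetative cells (-0.148, -0.106), without XRN1 in premeiotic cells (-0.233) and at 60 min of Ccr4 induction against control (-0.194). With at least 100 counts, the libraries fragmented before ligation stood at -1.18 without XRN1 (main -0.401) and at -0.899 in meiotic against vegetative wild type (main -0.493). The rank correlation of median tail with hours was -0.591 without 0 h. With an estimated correlation, RNA lists past the threshold numbered 1 at 5 h, 1 at 9 h, 2 and 2 from 1 h, 5 and 3 from 7 h and 2 for the difference, and tail lists 0 in the return to growth.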

Other observations

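No tests were made in this part, so none were chosen only after the result was seen, but the comparisons of stages within a strain were added after the data were seen. Wild-type cells differed between stages in more than the meiotic genes. From vegetative to premeiotic growth, gluconeogenesis genes stood 8.14 log2 units higher and stress genes 3.04 higher (both percentile 100), and ribosomal protein genes at -3.83 (percentile 0). The acetate transporter gene ADY2 stood at 15900 CPM at 5 h in SPO against 4.99 in vegetative growth. Tails of the ribosomal protein genes were longer while their RNA was lower, by 13.7 nt in premeiotic cells and 7.37 nt in meiosis (both percentile 100), with RPL9A at 48.7 nt in meiosis against 24.9 nt and RPS21B at 53.8 nt in premeiotic cells against 31.8 nt. Stress genes went the other way in tail length, at -9.74 nt in premeiotic cells (percentile 0.02), and early meiotic genes stood at -17.0 nt in meiosis (percentile 0).

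Within each mutant the median tail was shorter at 5 h in SPO than in vegetative growth, at -12.8 nt without CCR4, -6.17 nt without POP2 and -4.57 nt without XRN1, against -1.20 nt in wild type. Weighted by tags these differences were -5.92, -0.807 and -5.41 nt, and 8.08 nt in wild type, whose direction turned. At 5 h in SPO middle meiotic genes stood 111-fold, 99.1-fold and 57.9-fold below wild type by median in these mutants, with low counts set to the floor. The nitrogen uptake genes GAP1 and DAL5, which cells express when good nitrogen sources run out, stood high in mutants at 5 h in SPO, GAP1 at 3885 against 135 CPM without CCR4 and DAL5 at 4336 against 126 CPM without POP2. FIT1, of iron retention, stood at 3341 against 196 CPM in premeiotic cells without CCR4. Tags assigned to XRN1 numbered 273 in the control of the degron experiment and 17 and 21 in the degron strain. In the Ccr4 experiment tags assigned to CCR4 numbered 97, 81 and 714.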
